A study of Mus musculus with 8 samples.

How the data were processed

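RNA sequencing was analysed for 8 libraries of mouse C2C12 cells, 4 transfected with siNC and 4 with siFam129b, all labelled as muscle differentiation. Per the labels' protocols, cells were grown with 10% fetal bovine serum and differentiated with 2% horse serum, siRNA was delivered by lipid transfection, and libraries were made from 1.3 µg of total RNA after poly(A) selection and fragmentation to between 300 and 350 bp. The time in differentiation medium, the siRNA sequence and the number of siRNAs are not given in the sources used here.

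The deposited table holds 1 FPKM value per gene and library, made by the authors. The submitters' processing notes list the genome build mm9; the aligner, the counting tool and the annotation are not given in the sources used here. No coordinates are printed, since the reference used here is of another build. Columns carry a letter and a number; those starting with F were matched to the samples titled for the Fam129b siRNA and those starting with N to siNC, by letter and replicate number. The siNC descriptions also carry the letter N, while those of the Fam129b siRNA samples carry another code, so the match of the F columns rests on the titles alone. No mitochondrially encoded gene is among the rows used here, so that list was not tested. FPKM divides by gene length and library total, so a change in the composition of 1 library moves all its genes.

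Of 21879 genes, 5400 were at 0 in every library. For 16478 of the other 16479 the values in the 8 libraries were ratios of whole numbers, within 0.001 of a read. The smallest whole numbers in each ratio were taken as the reads, so a gene whose reads share a common factor is undercounted. A gene with a value in only 1 library comes out whole by construction. The totals, as lower bounds, were 31466869, 31678866, 36031688 and 32717085 for siFam129b libraries 1 to 4 and 34407536, 34441188, 33330856 and 34938157 for siNC. Neat1 was the exception. The recovered reads set relative depth and implied gene length; intervals from them would cover counting error only. No 2 libraries agreed within sampling noise: the lowest chi-square per gene between libraries of a group was 5.58, where sampling alone gives about 1.

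The main test was limma (version 3.58.1, R 4.3.3) with a mean-variance trend on log2(FPKM + 1), over 11025 genes with a mean of at least 1 FPKM, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates those of low genes. Fam129b was also tested by an exact two-sided permutation test over 70 assignments. Of 41 gene lists, 30 with at least 5 tested members entered camera with a preset correlation of 0.01, with camera using an estimated correlation and fry beside it. The design, lists, rule for named genes and 19 alternative fits, with further thresholds and list tests, were set before the data were examined. The named genes were the Niban family, 10 fixed muscle and proliferation genes, the genes with the largest called changes (none were called), and up to 4 members of each list described, by smallest p.

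After the data were seen, 9 further fits were added, since siFam129b library 4 and replicates 1 and 2 against 3 and 4 stood apart: the latter as a covariate, the same without siFam129b library 4, each pair of replicates alone, array weights with the covariate, voom on recovered reads, removal of length trends or of length and GC trends, and the table without Neat1. The labels name no batch, so the replicate split comes from the data. Results of these fits do not have the standing of the main test. GC content came from GENCODE M21 transcripts, matched by symbol for 97.2% of tested genes.

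The tests were tried on simulated data, with 11024 real genes at their real means, depths and residual spread, independent between genes. With 200 planted changes, beside a log2 shift of -0.5 in the sarcomere list, limma recovered 38.8% of genes changed 1.5-fold. It recovered 80.6% at 2-fold and 100% at 4-fold in the design of 4 against 4, and called 9 of 10793 unchanged genes. Each gene had the same spread in every library, so no simulated library stood apart as siFam129b library 4 does. These shares therefore do not give the power of the test on the real data. Negative binomial count models were not run, and voom on the recovered reads was used instead.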

Results

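Messenger RNA was measured by sequencing in C2C12 cells, a mouse myoblast line that stops dividing and fuses into myotubes when serum is lowered. The cells were transfected with a control siRNA (siNC) or with an siRNA against Fam129b (siFam129b), a member of the Niban family of cytoplasmic proteins, and all 8 samples carry the label of muscle differentiation. There were 4 libraries per group. The whole reads recovered from the deposited values, taken as the smallest that give the ratios, came to between 31466869 and 36031688 per library. The labels do not say whether the 4 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The stated aim was to learn what Fam129b does in muscle atrophy, and the comparison asks which transcripts differ when it is depleted.

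Fam129b itself was lower in every siFam129b library than in every siNC library. Its level was 98.5 ± 19.9 FPKM (SD, n = 4) with siFam129b and 168 ± 11.6 FPKM (SD, n = 4) with siNC, so 58.8% remained. The 4 siFam129b libraries held 91.6, 87.0, 87.3 and 128 FPKM, and the 4 siNC libraries 154, 163, 179 and 175 FPKM. The log2 difference was -0.78, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 can give. siFam129b library 4 kept 76.5% of the siNC mean, against 52.8% for libraries 1 to 3. In limma over all tested genes the adjusted p of Fam129b was 0.784 with library 4 and 0.00176 without it, and Fam129b also passed with array weights (adjusted p = 5.14e-05) and after quantile normalization (adjusted p = 0.0294). Array weights gave siFam129b library 4 a weight of 0.05, against 0.72 or more for the others, so that fit nearly leaves it out. The paralogs Fam129a and Fam129c stayed low in both groups, at 3.71 ± 0.603 and 1.85 ± 0.333 FPKM (SD, n = 4) with siFam129b, and neither passed the test.

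**Figure D1:**
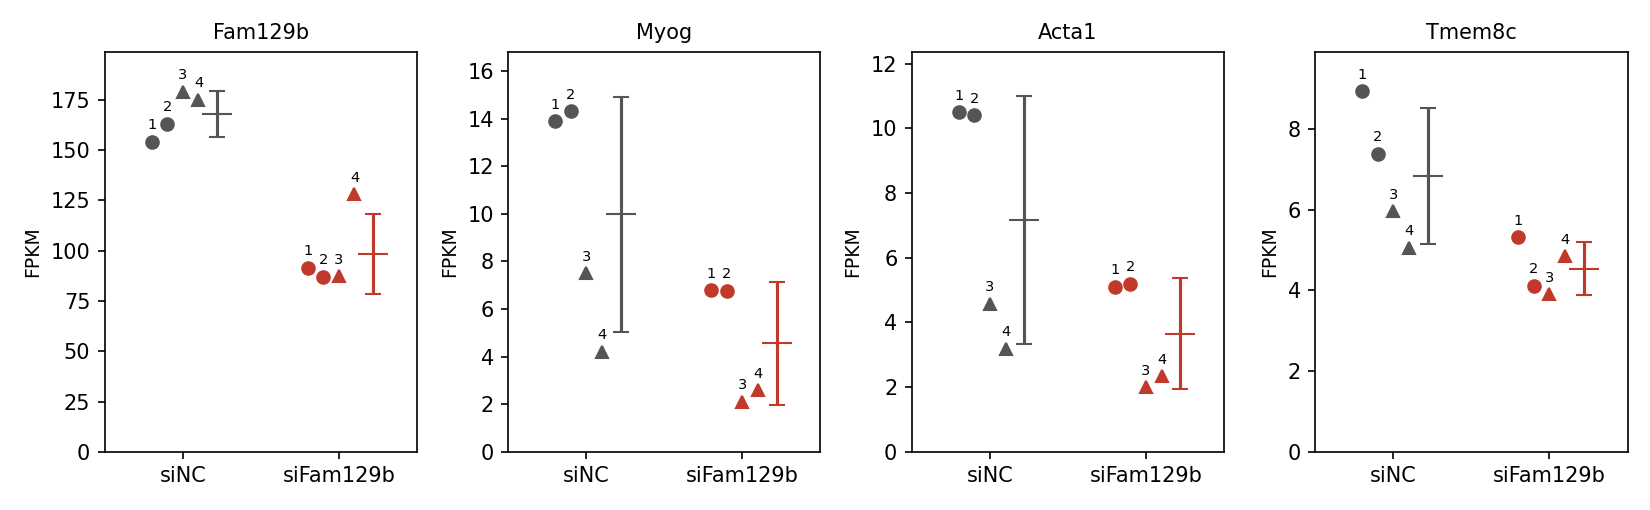
FPKM (vertical axis, linear, from 0) of Fam129b, Myog, Acta1 and Tmem8c in each library of the siNC and siFam129b groups; numbers are replicates, circles replicates 1 and 2, triangles replicates 3 and 4, and bars the mean and SD of 4 libraries. Fam129b lies between 87.0 and 128 FPKM in the siFam129b libraries and between 154 and 179 FPKM in the siNC libraries, while Myog overlaps between the groups.

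No gene of the 11025 tested passed an adjusted p of 0.05 in limma. Genes at an unadjusted p under 0.05 numbered 274, of which 196 were higher and 78 lower with siFam129b, against 551 expected by chance. The count of 274 includes Neat1, whose values are the only ones in the table that are not multiples of whole reads; 273 remain without it. The count moved with single libraries: it was 125 without siNC library 4, 140 without siNC library 3, 475 without siFam129b library 4 and 762 without siFam129b library 3, the last above the 551 expected. limma voom on the recovered reads also called 0 genes, with 254 at an unadjusted p under 0.05. Leaving out siFam129b library 4 gave 1 call, Fam129b.

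Genes of the muscle contractile apparatus had lower values with siFam129b. Of 31 tested sarcomere genes, 23 lay below 0 and 8 above, with a mean log2 difference of -0.22, and 0 passed singly, over all genes or adjusted over the list alone. Examples were Ttn, the giant spring protein of the sarcomere, at a log2 difference of -0.49 ± 0.15 (SE) and Klhl41 at -0.59 ± 0.23 (SE). Xirp1 had -0.22 ± 0.09 (SE) and Tmod1, which caps actin filaments, -0.45 ± 0.20 (SE). Ttn, Klhl41 and Tmod1 were near the filter of 1 FPKM, averaging 0.813, 0.89 and 0.765 FPKM with siFam129b. In siNC they averaged 1.53, 1.85 and 1.48 FPKM. Ttn was at 0.347 FPKM in siFam129b library 4, against 0.866 to 1.06 FPKM in the other siFam129b libraries. The list was called lower by camera with the preset correlation (adjusted p = 0.00173), and the call was lost with an estimated correlation (adjusted p = 0.708 with an estimated correlation). It was also lost without siNC replicate 1, where the mean was -0.12 (adjusted p = 0.0914), without siFam129b replicate 3, where it was -0.15 (adjusted p = 0.21), and among genes with a mean FPKM of at least 5, where it was -0.09 (adjusted p = 0.641). In siNC the list stood 0.49 higher in replicates 1 and 2 than in 3 and 4, so leaving out 1 library moved the mean by imbalance too. Without siNC replicate 3 or 4 or siFam129b replicate 1 or 2 the mean lay further from 0, between -0.328 and -0.256. In replicates 1 and 2 alone, a fit added after the data were seen, the mean was -0.35, and in 3 and 4 alone it was -0.09 with the call lost (adjusted p = 0.104).

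Myog, the transcription factor that drives terminal differentiation of myoblasts, stood at 4.56 ± 2.58 FPKM (SD, n = 4) with siFam129b and 10.0 ± 4.97 FPKM (SD, n = 4) with siNC. Acta1, skeletal muscle actin, stood at 3.66 ± 1.72 and 7.16 ± 3.83 FPKM (SD, n = 4), and Tmem8c, the fusion protein myomaker, at 4.54 ± 0.658 and 6.83 ± 1.69 FPKM (SD, n = 4). Each of the 3 had an adjusted p of 0.784 in limma. Libraries of both groups also differed by replicate number. In replicates 1 and 2, Myog averaged 6.79 FPKM with siFam129b and 14.1 FPKM with siNC, and in replicates 3 and 4 it averaged 2.34 and 5.86 FPKM. Acta1 averaged 5.14 and 10.4 FPKM in replicates 1 and 2, and 2.17 and 3.88 FPKM in replicates 3 and 4. Myod1, the myoblast determination factor, averaged 37.0 ± 4.73 FPKM (SD, n = 4) with siFam129b and did not pass the test (log2 difference 0.13 ± 0.13, SE).

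In a fit chosen after the data were seen, without siFam129b library 4 and with replicates 1 and 2 against 3 and 4 as a covariate, limma called 5 genes. Fam129b (log2 -0.90, adjusted p = 1.15e-05), Acta1 (-0.81, adjusted p = 0.0142) and Myog (-1.02, adjusted p = 0.0227) fell. Anxa8 (0.46, adjusted p = 0.0142) and Neat1 (0.61, adjusted p = 0.0108) rose; the values of Neat1 are not multiples of whole reads, and both genes are named after their values were seen. This was 1 of 9 fits added after the data were seen: 5 of the 9 called 0 genes and the others between 1 and 50.

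Genes of the muscle regulatory, calcium handling, fusion and neuromuscular junction lists were mostly below 0 with all 8 libraries, and none of these lists was called in the planned test. Of 14 myogenic regulators 11 were below 0 (camera adjusted p = 0.0529), of 14 calcium handling and excitation coupling genes 10 (adjusted p = 0.061), of 20 myoblast fusion genes 15 (adjusted p = 0.061) and of 19 neuromuscular junction genes 14 (adjusted p = 0.126). siFam129b library 4 differed from the other siFam129b libraries by -0.74 on the log2 scale for myogenic regulators and by -0.30 for calcium handling. Without that library 9 of the 14 myogenic regulators were above 0 (mean -0.04), 10 of the 20 fusion genes were below 0 and 11 of the 19 neuromuscular junction genes. Calcium handling then also had 10 of 14 below 0, with a mean of -0.09 (camera adjusted p = 0.146) against -0.16 with all 8 libraries. In fits added after the data were seen, calcium handling was called lower without that library and with the replicate covariate (adjusted p = 0.00312), in replicates 1 and 2 alone (0.00194) and with length and GC trends removed (0.00198), and myogenic regulators in replicates 3 and 4 alone, which include that library (mean -0.355, adjusted p = 0.00325). The replicate covariate on all 8 libraries called fusion (0.0499), regulators (0.0116) and calcium handling (0.0358). A planned fit with a replicate block called regulators (0.00638) and calcium handling (0.0202). The regulator, calcium handling and fusion lists were called lower without siNC library 3 or 4 or siFam129b library 1 or 2 (camera adjusted p from 0.00191 to 0.0436), and the junction list without siNC library 4 (0.0236) or siFam129b library 1 (0.0454). Each of these omissions unbalances replicates 1 and 2 against 3 and 4 between the groups. In siNC the regulator, calcium handling, fusion and junction lists stood 0.23, 0.28, 0.15 and 0.19 higher in replicates 1 and 2. Part of these moves away from 0 therefore followed from the imbalance. With no low-value filter the regulators (0.00695) and calcium handling (4.63e-05) were called, and after quantile normalization fusion (0.0155). None of these calls held with an estimated correlation (the smallest adjusted p with an estimated correlation, over all fits of the 30 lists, was 0.187). Myh3 and Ckm were near the floor: Myh3, embryonic myosin, was at most 2.55 FPKM and Ckm at most 0.984 FPKM in any library. The proliferation marker Mki67 averaged 80.8 ± 7.24 FPKM (SD, n = 4) with siNC. In every library Mki67 lay between 66.6 and 90.4 FPKM and Top2a, another cell cycle gene, between 132 and 165 FPKM. Acta1 was at most 10.5 FPKM, and 31 of the 63 fixed sarcomere genes reached a mean of 1 FPKM. Transcripts of dividing cells were thus abundant in both groups, far above Myh3, Ckm and Acta1. How far the cultures had differentiated was not tested.

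**Figure D2:**
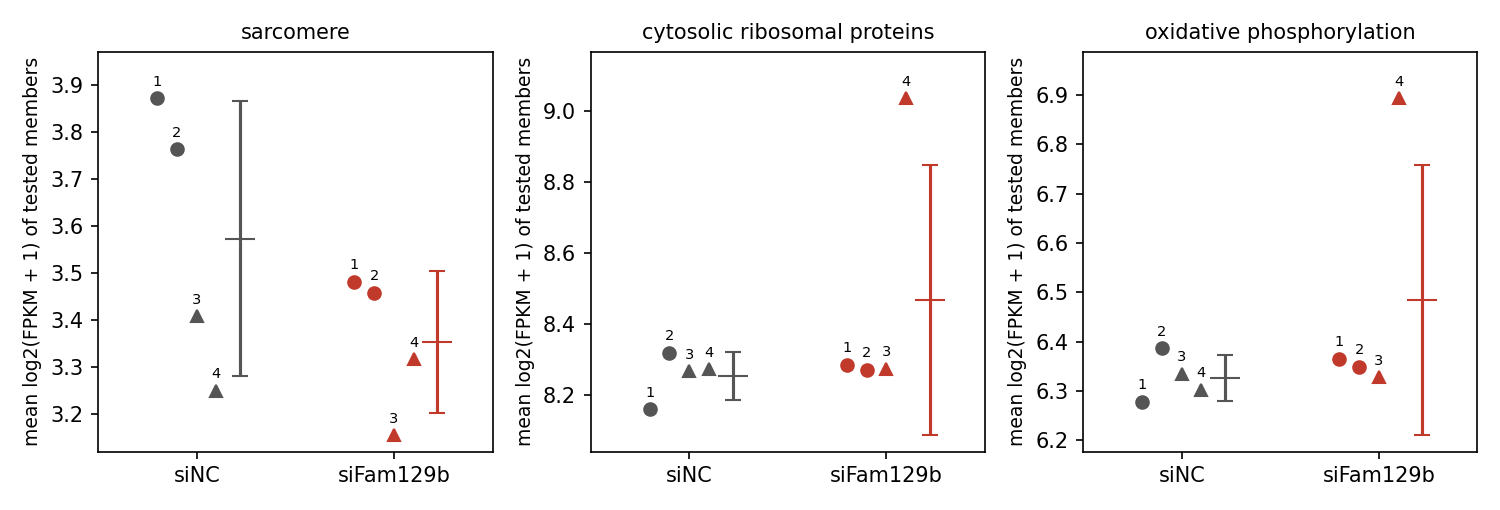
Mean log2(FPKM + 1) of the tested members (vertical axis, not from 0) of the sarcomere, ribosomal protein and oxidative phosphorylation lists in each library; numbers are replicates, circles replicates 1 and 2, triangles replicates 3 and 4, and bars the mean and SD of 4 libraries. siFam129b library 4 reaches 9.04 for ribosomal proteins, against 8.27 to 8.29 in the other siFam129b libraries.

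Ribosomal protein and respiratory chain genes had higher values with siFam129b. Cytosolic ribosomal protein genes averaged 0.21 higher on the log2 scale, with 72 of 76 above 0 (camera adjusted p = 3.84e-11; adjusted p = 0.708 with an estimated correlation). Oxidative phosphorylation genes averaged 0.16 higher, with 38 of 44 above 0 (adjusted p = 2.68e-05; adjusted p = 0.708 with an estimated correlation); Cox6a1 stood at 360 ± 110 FPKM (SD, n = 4) with siFam129b. siFam129b library 4 lay 0.76 above the other siFam129b libraries for ribosomal proteins and 0.55 above for oxidative phosphorylation. Without it the ribosomal mean was 0.02 (adjusted p = 0.0271; adjusted p = 0.736 with an estimated correlation) and the oxidative phosphorylation mean 0.02 (adjusted p = 0.579), so the latter call ended, as it did with array weights (adjusted p = 0.406). With length and GC trends removed, in a fit added after the data were seen, both calls ended (adjusted p = 0.214 for ribosomal proteins and 0.906 for oxidative phosphorylation). In replicates 1 and 2 alone the ribosomal mean was 0.04 (camera adjusted p = 0.00237, or 0.759 with an estimated correlation) and the oxidative phosphorylation mean 0.02 (adjusted p = 0.325). In replicates 3 and 4, which include siFam129b library 4, they were 0.39 and 0.29. Mean log2 levels of the ribosomal list were 8.271 to 8.285 in siFam129b libraries 1 to 3. These lay within the siNC range, which ran from 8.159 in siNC library 1 to 8.319 in siNC library 2, with libraries 3 and 4 at 8.267 and 8.272.

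Glycolysis genes averaged 0.11 higher, with 21 of 27 above 0 (camera adjusted p = 0.00154; adjusted p = 0.708 with an estimated correlation), and 0.07 without siFam129b library 4. The call ended after quantile normalization (adjusted p = 0.0948) and in replicates 1 and 2 alone, where the mean was 0.02 (adjusted p = 0.0724), against 0.20 in replicates 3 and 4, which include that library. Eno2, a neuronal enolase, had a log2 difference of 0.33 ± 0.11 (SE) and Ldha, lactate dehydrogenase, 0.23 ± 0.12 (SE). Interferon response genes averaged 0.13 higher, with 15 of 19 above 0 (adjusted p = 0.0238; adjusted p = 0.708 with an estimated correlation), among them Ifi35 at 0.31 ± 0.12 (SE). That call ended without siNC replicate 3 (mean 0.09, adjusted p = 0.119), siNC replicate 4 (0.065, adjusted p = 0.174), siFam129b replicate 1 (0.11, adjusted p = 0.0513) or siFam129b replicate 2 (0.11, adjusted p = 0.0914), while the mean was 0.20 without siNC replicate 1. It ended with no low-value filter (mean 0.06, adjusted p = 0.261), among genes with a mean of at least 5 FPKM, where the list mean was 0.14 (adjusted p = 0.0719), and with length trends removed (0.0708) or length and GC trends removed (0.0949). It also ended in replicates 1 and 2 alone, where the mean was 0.03 (adjusted p = 0.411), against 0.23 in replicates 3 and 4. In siNC the interferon list stood 0.31 higher in replicates 1 and 2 than in 3 and 4. Part of its moves with single libraries left out therefore followed from unbalanced replicates. Autophagy and lysosome genes averaged 0.06 higher, with 32 of 44 above 0 (adjusted p = 0.0256; adjusted p = 0.708 with an estimated correlation), led by Tfeb, a regulator of lysosomal genes, at 0.40 ± 0.14 (SE). That call ended when each library was rescaled to an equal sum, which brought the mean to -0.004 (adjusted p = 0.0945), after quantile normalization (0.131), with array weights (0.0909), without siFam129b library 4 (0.0909) and with length and GC trends removed (0.147). It ended too in replicates 1 and 2 alone (mean 0.03, adjusted p = 0.214) and in 3 and 4 alone (mean 0.09, adjusted p = 0.0916).

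Cell cycle genes were lower, with 34 of 48 below 0 and a mean log2 difference of -0.07 (camera adjusted p = 0.02; adjusted p = 0.708 with an estimated correlation). Mcm4, a subunit of the replicative helicase, had -0.24 ± 0.13 (SE), and Mki67, a proliferation marker, 76.6 ± 8.84 FPKM (SD, n = 4) with siFam129b and 80.8 ± 7.24 FPKM (SD, n = 4) with siNC. The list call ended without siNC replicate 3 (mean -0.053, adjusted p = 0.0671), siNC replicate 4 (-0.037, adjusted p = 0.171), siFam129b replicate 1 (-0.044, adjusted p = 0.225) or siFam129b replicate 2 (-0.059, adjusted p = 0.0902), and in replicates 3 and 4 alone (mean -0.085, adjusted p = 0.131). It held without siFam129b library 4 (44 of 48 below 0, mean -0.079, camera adjusted p = 1.51e-06) and in replicates 1 and 2 alone (mean -0.05, 0.00194). It also held with libraries rescaled to an equal sum (mean -0.133, 0.00064), where the median of all genes was -0.06. None of these calls held with an estimated correlation. For none of these lists was the difference between the replicate pairs tested. In siNC the cell cycle mean of replicates 1 and 2 minus that of 3 and 4 was -0.13. Part of the cell cycle moves toward 0 with single libraries left out therefore followed from unbalanced replicates. In all, camera with the preset correlation called 7 of 30 lists, 5 higher and 2 lower. After quantile normalization the split was 3 higher and 3 lower.

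The atrophy gene list was not called (33 tested, 20 above 0, adjusted p = 0.571). Fbxo32, a ubiquitin ligase of muscle wasting, stood at 4.58 ± 1.31 FPKM (SD, n = 4) with siFam129b and 5.08 ± 1.17 FPKM (SD, n = 4) with siNC, Trim63 was at most 0.0971 FPKM, and Mstn was listed at 0 in every library but siNC library 1. Proteasome genes (33 tested, 25 above 0) were not called (adjusted p = 0.192), and siFam129b library 4 lay 0.42 above the other siFam129b libraries for them; without it the list was called lower, at a mean of -0.05 (adjusted p = 0.00674; adjusted p = 0.68 with an estimated correlation). It was called higher without siNC library 4 (adjusted p = 0.0325), siFam129b library 1 (0.0126) or siFam129b library 2 (0.0436), with estimated-correlation adjusted p of 0.74, 0.633 and 0.72. In siNC the proteasome mean of replicates 1 and 2 minus that of 3 and 4 was -0.13. Part of these moves therefore followed from replicates left unbalanced between the groups. The other tested lists that were not called were extracellular matrix and cholesterol synthesis (adjusted p = 0.126 each), YAP targets (0.126), Wnt/beta-catenin targets (0.177), Nrf2 targets (0.192), heat shock (0.303), TGF-beta and BMP targets and the TCA cycle list (0.401 each), apoptosis (0.436), p53 targets and the unfolded protein and integrated stress response (0.513 each), focal adhesion and inflammatory targets (0.545 each), satellite and reserve cell genes (0.631), IGF, AKT and mTOR signalling (0.685), MAPK/ERK targets (0.847) and cell cycle exit (0.906). Of these, inflammatory targets were called higher without siFam129b library 4 (19 of 22 above 0, mean 0.14, adjusted p = 0.0202). With the replicate covariate added the mean was 0.07 (camera adjusted p = 0.0175). In siNC this list stood 0.48 higher in replicates 1 and 2 than in 3 and 4. Part of the larger mean without the covariate therefore followed from unbalanced replicates. Without siFam129b library 1, YAP targets were called lower (0.0375) and heat shock (0.0375) and Nrf2 targets (0.0372) higher. Nrf2 targets were also called without siNC library 4 (0.0494) and YAP targets in replicates 3 and 4 alone (0.00586). In siNC the mean of replicates 1 and 2 minus that of 3 and 4 was -0.17 for Nrf2 targets and -0.15 for heat shock. Part of their moves with single libraries left out therefore followed from unbalanced replicates. With an estimated correlation none of these calls held (the smallest adjusted p with an estimated correlation was 0.557).

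Markers of other cell types were mostly near the floor. Of 79 marker genes in 9 lists, 19 reached a mean of 1 FPKM: 4 each for fibroblasts and smooth muscle, 3 each for adipocytes and for osteoblasts and chondrocytes, 2 each for macrophages and neural cells, 1 for epithelial cells and 0 for endothelial cells and hepatocytes. None of the 9 lists had the 5 tested members needed for a test.

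siFam129b library 4 stood apart from the other 7 libraries. Its correlation with them over tested genes was 0.936 to 0.951, against 0.982 to 0.996 among the others (across genes, which are not independent replicates). Its FPKM values summed to 470385, against 391336 to 398292. The fifth of genes with the shortest implied length had a median log2 deviation of 0.46 in this library from the other siFam129b libraries, and the fifth with the longest -0.58. The main principal component, with 68.9% of the variance, separated it from the rest. The next, with 18.8%, separated replicates 1 and 2 from 3 and 4 in siNC and siFam129b libraries 1 and 2 from 3.

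**Figure D3:**
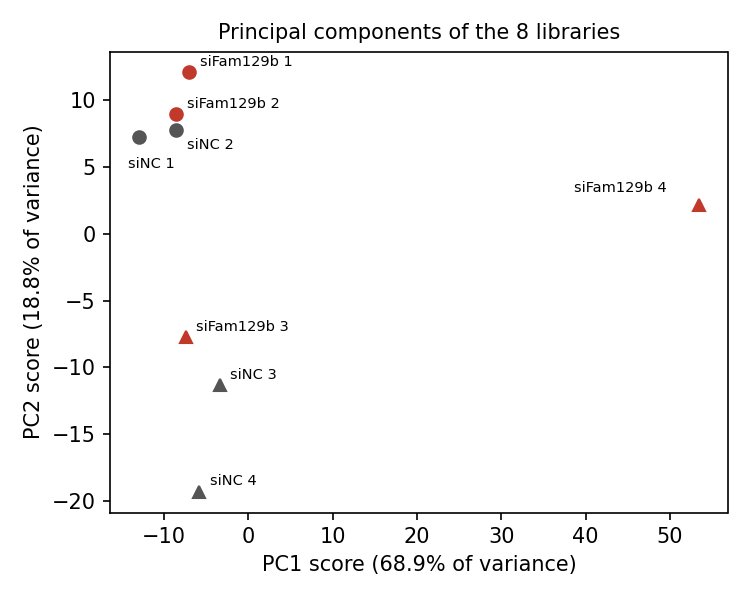
Scores of the 8 libraries on the main principal component (horizontal axis, 68.9% of the variance) and the next (vertical axis, 18.8%), over log2(FPKM + 1) of 11025 genes; grey is siNC, red siFam129b, circles replicates 1 and 2, triangles replicates 3 and 4. siFam129b library 4 lies at 53.5 on the horizontal axis and the other libraries between -13 and -3.4.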

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

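Tests of mislabelling, of the replicate difference, of the count of genes over other splits, of splits within replicates and of both explanations for Neat1 were chosen after the results were seen; the fit without siFam129b library 4 was planned, and the rule for reading it as a test of the sarcomere list was written afterwards. In a group of 4, chance marks about 1 in 20 groups as having a library far from the rest; 27 of 233 groups were marked, against 11.7 expected, and 20 of the 27 were in siFam129b library 4.

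In siFam129b library 4 the values far from the other siFam129b libraries were, in FPKM, Fam129b 128, Mef2a 11.4, Dock1 5.25, Hmmr 33.7, Rpl37a 382, Rpl38 142, Hexa 94.3, Psme4 19.7, Psmb3 181, Pdia6 282, Sdf2l1 45.5, Cd44 67.7, Gstm1 141 and Fth1 3730, with an FPKM sum of 470000. The mean log2 level of 5 lists also lay apart there: Wnt/beta-catenin targets 3.48, YAP targets 4.09, oxidative phosphorylation 6.89, TCA cycle, fat oxidation and mitochondrial biogenesis 5.43, and cytosolic ribosomal proteins 9.04. Among siNC libraries, Mstn in library 1 (0.0215), Rps27 in library 1 (164), Top2a in library 2 (156), Blvrb in library 2 (29.4), Dok7 in library 3 (2.67), Lama5 in library 4 (48.4) and Tfeb in library 4 (4.91 FPKM) lay apart from the other 3.

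siFam129b library 4 differed from the other siFam129b libraries with an SD over genes of 0.582 on the log2 scale. Removing trends with gene length and GC content brought this to 0.389, against at most 0.215 in any other library, which argues against these trends as the whole cause while they account for part. RNA from a cell type with abundant transcripts that C2C12 cells lack is argued against by 0 genes under 0.1 FPKM in the other 7 libraries and at 10 FPKM or more in this one. Its Fam129b level was 128 FPKM, below the lowest siNC library at 154 FPKM, and 112 FPKM with the trends removed. That test rests on Fam129b alone, in a library whose genes strayed with an SD of 0.389 even with the trends removed. A mislabelled siNC library therefore stays open. A difference in RNA quality or library preparation, and a biological difference of this culture, stay open and were not tested.

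Sarcomere genes were lower with siFam129b by a mean log2 difference of -0.22; siFam129b library 4 and length and GC trends are argued against as the cause, since the mean was -0.21 without that library (camera adjusted p = 0.00213; adjusted p = 0.672 with an estimated correlation) and -0.29 with the trends removed (adjusted p = 2.92e-05; adjusted p = 0.851 with an estimated correlation). An additive difference between replicates 1 and 2 and replicates 3 and 4 is argued against, since by replicate number each group holds 2 libraries of each part. siFam129b library 4 was placed by its number alone. On the component with 18.8% of the variance it lay at 2.2, between replicates 1 and 2 (7.3 to 12.1) and the other libraries (-19.3 to -7.7). Counting it with replicates 1 and 2, where the siNC list stood higher, would not account for a lower siFam129b mean. Without siFam129b library 4 the parts are unequal, and the replicate covariate moved the mean to -0.278 (camera adjusted p = 3.33e-12, or 0.343 with an estimated correlation). In siNC the list stood 0.49 higher in replicates 1 and 2, so a move away from 0 followed from the imbalance and is not evidence. The mean was -0.347 in replicates 1 and 2 and -0.093 in replicates 3 and 4, and whether the difference is present in both parts cannot be told apart with 2 libraries per group in each. Over the 35 splits of the 8 libraries chance cannot be excluded, since 9 gave a mean as far from 0, the highest other being 0.36, for replicates 1 and 2 against 3 and 4, against 0.22; of the 18 splits that keep these replicates balanced 2 did, the highest other being 0.25, and 18 are too few for a share under 0.05. The knockdown remains an open explanation, as a hypothesis, beside an effect of this siRNA on other transcripts.

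The Neat1 values are not multiples of whole reads: the smallest worst distance from whole numbers over the 8 libraries was 0.0542 of a read. Rounding to 9 decimals is argued against, since 300 of 300 other genes rounded that way stayed whole. Fractional counting of shared reads is argued against, since 1 gene of the table alone was affected. How these values were made stays open, and no biological explanation was tested. The gene has the smallest p in the table (log2 difference 0.59 ± 0.09, SE; limma adjusted p = 0.739).

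For the count of genes, a real count of 0 is reached by all 35 of the 35 splits by construction, so they say nothing about chance; the highest other count was 423, for replicates 1 and 2 against 3 and 4, which points to a structure of the samples. For lists, 24 of 35 splits called at least the real 7, the highest other being 18, so chance cannot be excluded; of the 18 balanced splits 7 did, the highest other being 10, and 18 are too few for a share under 0.05. The fit without siFam129b library 4 and with the replicate covariate was picked after the data were seen. In it 1 of 34 splits of 7 libraries, the real one, called as many as 5 genes, the highest other being 2. The 5 include Fam129b, the target of the siRNA, and Neat1. Chance is therefore not excluded for the other genes, although 1 of 34 is a share under 0.05. For 1 further split no fit was possible. Of the 34, 18 keep the real numbers of libraries from replicates 1 and 2 and from 3 and 4. Among these 18, the real split again was the 1 with 5 genes and the highest other gave 2, and 18 splits are too few for a share under 0.05.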

How the results depend on the processing

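The alternatives with a replicate covariate, single pairs of replicates, voom, trend removal or Neat1 left out were chosen after seeing the data. Fam129b was lower in every fit. Leaving out each replicate in turn gave log2 differences from -0.91 to -0.73; 3 against 4 cannot go below an exact p of 0.0571, so these lose the threshold by design. So do replicates 1 and 2 alone (-0.82) and 3 and 4 alone (-0.74), with an exact p of 0.333. The limma adjusted p of Fam129b ranged from 3.75e-07 to 0.912 over the fits, that of Myog from 0.000784 to 0.96, that of Acta1 from 0.000689 to 0.96 and the camera adjusted p of the sarcomere list, with the preset correlation, from 4.04e-15 to 0.641.

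The count of genes was 0 under every planned fit except quantile normalization (1, lower), array weights (2: 1 higher, 1 lower) and leave-one-out, which ranged from 0 to 1 in all and for lower genes. Added fits gave 10 genes in replicates 1 and 2 alone (2 higher, 8 lower), 5 without siFam129b library 4 and with the covariate (2 higher, 3 lower), 50 with array weights and the covariate (24 higher, 26 lower) and 1 (lower) with length and GC trends removed. Neat1 is among the 2, the 5, the 10 and the 50. The other added fits gave 0. The cause was not tested.

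Against 7 lists (5 higher, 2 lower), leave-one-out gave 6 to 13 lists, 4 to 7 higher and 1 to 6 lower; the most were 13 without siFam129b replicate 1 and 11 without siNC replicate 4. Leaving out 1 library also unbalances replicates 1 and 2 against 3 and 4 between the groups, which moves lists that differ between these replicates. An estimated correlation and fry each called 0 lists, 0 higher and 0 lower, and an estimated correlation called 0 of the 30 in every other fit too. Lower lists numbered 4 with no low-value filter and 1 among genes with a mean FPKM of at least 5. Quantile normalization left 3 higher. The covariate gave 11 lists (5 lower); without siFam129b library 4 it gave 5 lower. Replicates 1 and 2 alone gave 2 higher and 4 lower, and array weights with the covariate 3 higher and 4 lower. Removing length trends left 3 higher, and removing length and GC trends 2 higher and 4 lower. The proteasome list turned, with means of -0.048 to 0.106 over leave-one-out (lowest without siFam129b library 4) and -0.03 without that library and with the covariate. Oxidative phosphorylation turned in the camera direction with array weights and the covariate, at a mean of 0.006. The cause was not tested.

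Whether replicate numbers pair the samples stays open. Same-numbered deviations correlated at 0.53, 0.25, 0.04 and 0.12, and not every library correlated best with its own number. These deviations are from group means that include siFam129b library 4. By chi-square per gene, siFam129b libraries 2 and 3 lay nearest the same-numbered siNC library (6.29 and 8.91). Library 1 lay nearer siNC library 2 (8.16) than siNC library 1 (11.16). A replicate block called 0 genes and 9 lists, 4 of them lower, among these myogenic regulators (adjusted p = 0.00638) and calcium handling (0.0202); the replicate covariate called these too (0.0116 and 0.0358). Of 80 named genes, 10 (Neat1 among them) passed the threshold in at least 1 fit. Negative binomial count tests, planned in case reads could be recovered, were not run, although reads were recovered. The deposited unit is FPKM, and voom on the recovered reads stood in. At this depth the spread between libraries, not counting error, limits the precision.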

Other observations

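Extracellular matrix genes were called higher without siFam129b library 4 (44 of 50 above 0, mean log2 difference 0.11, camera adjusted p = 6.16e-06; adjusted p = 0.672 with an estimated correlation), and cholesterol synthesis genes lower (21 of 25 below 0, mean -0.06, adjusted p = 0.00385; adjusted p = 0.672 with an estimated correlation). In the planned test with all 8 libraries neither list was called (adjusted p = 0.126 each). Array weights, which nearly leave out siFam129b library 4 (weight 0.05, against 0.72 or more for the others), called both (adjusted p = 1.81e-05 and 0.00345, or 0.768 and 0.703 with an estimated correlation). The extracellular matrix list was also called without siNC library 1 (mean 0.08, adjusted p = 0.00448) or 2 (mean 0.07, adjusted p = 0.0177), with adjusted p of 0.756 and 0.73 with an estimated correlation. It was not called, and its mean lay below 0, without siNC library 4 (-0.042, adjusted p = 0.929), siFam129b library 1 (-0.034, adjusted p = 0.908) or siFam129b library 2 (-0.018, adjusted p = 0.705), with libraries rescaled to an equal sum (-0.036) and after quantile normalization (-0.004). These fits were planned; removal of length and GC trends, added after the data were seen, called both lists (adjusted p = 0.00345 and 0.00366; 0.851 and 0.321 with an estimated correlation), and the replicate covariate the extracellular matrix list (0.0494; 0.632 with an estimated correlation). Without siFam129b library 4 and with the replicate covariate, also added afterwards, the extracellular matrix mean was 0.07 (camera adjusted p = 6.9e-07, or 0.557 with an estimated correlation). In siNC that list stood 0.29 higher in replicates 1 and 2 than in 3 and 4. Part of its moves with single libraries left out therefore followed from unbalanced replicates. The 2 lists were singled out after their values were seen.

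In siNC, the sarcomere list stood 0.49 higher in replicates 1 and 2 than in 3 and 4 on the log2 scale, the inflammatory and NF-kB target list 0.48 higher and the interferon response list 0.31 higher. No label names a difference between these replicates.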
